A study of Mus musculus with 6 samples.

How the data were processed

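RNA from mouse embryonic stem cells of the E14 line was profiled on 6 expression arrays, with 2 arrays for each of 3 groups: cells transfected with a pool of non-specific siRNAs, cells transfected with siRNA 1 against p/CIP, and cells transfected with siRNA 2 against p/CIP. p/CIP is the protein of the gene Ncoa3, a coactivator of nuclear receptors. Per the labels, RNA was isolated with a Qiagen RNeasy kit, and each title gives the siRNA and a replicate number. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

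The deposited values are on a log2 scale, with 1 value for each of 35556 probe sets on each array. The log base was inferred from their range of 2.69 to 14.6 and is stated in neither the labels nor the table; if the base were another, folds would change and tests would not. Partek is named in the submitters' processing notes, while its version and the background correction, summarization and normalization are not given in the sources used here. Array medians lay between 7.77 and 7.84, and no background values or detection calls were used, so the number of arrays, not a depth, limits the precision. The median SD between the arrays of a group was 0.1 on the log2 scale.

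Gene names came from GEO's platform annotation. It gave 1 symbol for 21789 probe sets and several for 1621, which were left unnamed, and 12146 probe sets were not listed in it. A gene was a symbol that a probe set held alone, and the probe set with the highest mean over the arrays stood for each of the 999 genes with more than 1. This left 19938 genes. No symbol needed updating against RefSeq. Genomic coordinates are not reported, since no build is named in the table.

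All 3 groups were fitted together, with 1 coefficient per group, in limma 3.58.1 under R 4.3.3 (lmFit, and eBayes without trend or robust options), on the deposited log2 values with no filter. The fit had 3 residual and 3.84 prior degrees of freedom. Contrasts were the mean of both p/CIP siRNAs against control, each siRNA against control, and siRNA 2 against siRNA 1. Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 over the 19938 genes were called. Every adjusted p of a gene is limma's, and the error beside a change is its standard error.

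Before the data were examined, 28 gene lists were fixed from general knowledge of stem cells, of other cell types a culture could hold, of signalling and of stress. For 1 of them, the mitochondrial transcripts, 0 members were measured, and the other 27 were tested. The 28 lists held 650 entries, of which 573 were measured. Lists were tested with limma's camera at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, adjusting over the 27 lists of a contrast. A list call means an adjusted p under 0.05 from camera at the preset correlation. In the estimated-correlation version, 0 of the 27 lists passed in any contrast, with or without the replicate block. For primed epiblast markers and both siRNAs, the estimate was -0.0206. Even so, the unadjusted camera p was 0.0755 in this version and 0.0143 at the preset. So p rose there without a higher correlation, and not passing in this version does not show that a list was unchanged. By fry without the replicate block, no list passed in any of these contrasts between groups. The lowest fry adjusted p was 0.256 for both siRNAs, 0.235 for siRNA 1, 0.164 for siRNA 2 and 0.058 between the siRNAs. Members were counted both over all genes and adjusted over the list alone.

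Genes were named by a rule fixed at the same time. It took Ncoa3; up to 8 called genes with the largest changes in each direction for both siRNAs together and up to 5 for the other contrasts, with no overlap between the arrays compared and a brighter mean above the median gene level of 7.81; where none passed, the 5 of smallest p, said not to pass; up to 4 members of smallest p from each list called and from 3 lists always; and Pou5f1, Sox2, Nanog, Klf4, Esrrb and Tbx3. Predicted and olfactory genes were passed over. Genes named outside the rule are said to be chosen after their values were seen.

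Whether equal replicate numbers pair the arrays was checked before the fits were compared. Across genes, deviations from the group means of arrays with the same number correlated at 0.464 between control and siRNA 1, 0.407 between control and siRNA 2, and 0.461 between the siRNAs. All 3 lie over 0.1, so the numbers were taken to pair the arrays. With 2 arrays per group the numbering sets only the signs, and grouping by array code gave -0.464, 0.407 and -0.461. Positive values in all 3 can thus arise by chance, and the check is weak. This pairing comes from the data, as the labels do not say that a number marks a shared culture or day. The fit without the block stayed the main one, as fixed beforehand, and the value with the replicate number as a block is given where it changes a call or a count by over 1.5 times.

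Because both siRNA comparisons share the 2 control arrays, correlations between them were set beside 100 simulations of unchanged groups against the same controls. The 2 control arrays were not split between the siRNA comparisons, so agreement without shared controls was not measured.

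The gene test was tested on simulated data, in 20 runs with 200 of the 19938 genes changed. For both siRNAs against control, 20% of changes of 0.5 on the log2 scale were recovered, 95.3% of changes of 1, 99.1% of 1.5 and 99.7% of 2, and 3.83% of calls were false. For siRNA 1 against control the shares were 8%, 88.4%, 97.8% and 99.5%. The runs called 163 and 153 genes on average in these comparisons, against 14 and 14 in the data. An adjusted p passes more easily where more genes are changed, so these shares do not carry over to the data. With siRNA 2, for example, Ncoa3 at -1.49 did not pass in the data (limma adjusted p = 0.0742). A simulated list of 36 genes lowered by 0.25 reached an unadjusted camera p under 0.05 in 20 of 20 runs, with the preset and with an estimated correlation. An unchanged list did so in 0 of 20. Noise was drawn separately for each gene, so these lists held no correlation between genes. The runs therefore do not show how either version behaves on lists whose members vary together.

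Alternatives covered quantile normalization, alignment of array medians, filters on dim genes, the probe set or mean that stands for a gene, the test of every probe set, the variance model, an unmoderated linear model, array weights, a block on the replicate number or on the array codes, other thresholds, the arrays in the fit, and each array left out in turn. Cyclic loess, cyclic loess with the replicate block, and the replicate block without array siRNA 1 replicate 2 were added after seeing the data, because that array has the narrowest range of values.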

Results

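The study asked which transcripts depend on p/CIP in mouse embryonic stem cells, by lowering it with 2 different siRNAs. p/CIP, also called SRC-3 or AIB1, is encoded by Ncoa3 and belongs to the p160 family of coactivators, which bind nuclear receptors and recruit histone acetyltransferases. E14 is a feeder-independent mouse embryonic stem cell line. Each of the 3 groups (control siRNA, siRNA 1 and siRNA 2) had 2 arrays. Pearson correlations between pairs of arrays across the 19938 genes ran from 0.991 to 0.998. Array siRNA 1 replicate 2 stood apart from the rest: its interquartile range was 3.13 on the log2 scale, against 3.33 to 3.45 on the other 5 arrays, and its mean correlation with them was lowest, at 0.994.

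Both siRNAs lowered their target to the same level. Ncoa3 read 12.33 and 12.28 on the control arrays, 10.71 and 10.93 with siRNA 1, and 10.71 and 10.92 with siRNA 2. Over both siRNAs it fell 2.81-fold, to 35.6% of control (log2 change -1.49, standard error 0.0964, limma adjusted p = 0.0287, lower in 4 of 4 knockdown arrays than in both controls). The log2 change was -1.49 with each siRNA, with an adjusted p of 0.0452 for siRNA 1. For siRNA 2 it was 0.0742, and 0.048 with the replicate block. Between siRNA 2 and siRNA 1, Ncoa3 differed by -0.00 (95% interval -0.27 to 0.26). The pooled change stayed between -1.54 and -1.43 when any 1 array was left out. Its adjusted p passed 0.05 without control replicate 1 (0.62), control replicate 2 (0.248), siRNA 2 replicate 1 (0.146) or siRNA 2 replicate 2 (0.0969).

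For both siRNAs together against control, the genes that fell included 2 of the core and naive pluripotency list. Nr0b1 (Dax1), an orphan nuclear receptor of naive stem cells, fell 1.83-fold (log2 change -0.87, standard error 0.0727, adjusted p = 0.0347). Tbx3, a T-box factor that supports naive pluripotency, fell 1.88-fold (-0.91, standard error 0.0926, adjusted p = 0.0388). Kit, the receptor of stem cell factor, fell 1.8-fold (adjusted p = 0.0347). The largest falls after Ncoa3 were those of Inhbb, which encodes the activin beta-B subunit (2.3-fold, standard error 0.0973 on the log2 scale), Necab1, a calcium-binding protein (2.27-fold), and H2-M5, a class I-like histocompatibility gene (2.02-fold); the cytochrome P450 gene Cyp2b23 fell 1.86-fold, all 4 with adjusted p = 0.0347.

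In all, 14 genes were lower and 0 were higher. The other 6 of the 14, chosen after their values were seen, were Islr2 (-0.84), Ntn1, which encodes netrin-1 (-0.83), Porcn, the acyltransferase that WNT proteins need for secretion (-0.81), the hedgehog effector Gli2 (-0.81), the peptidase gene Dpp4 (-0.80) and Olfr153 (-0.67). The replicate block gave 62 lower and 6 higher genes, the 14 among them. At an unadjusted p under 0.05 there were 969 lower and 770 higher genes, against 997 by chance in all, and an unmoderated linear model called 0. No rise passed. Of those nearest to it, Fgf5, a growth factor of primed epiblast, was 1.59-fold higher (log2 change 0.67, standard error 0.0723, adjusted p = 0.053, and 0.0269 with the replicate block). Values for Ap3b2 were 0.51 higher (0.125, and 0.0471 with the block), for Ahnak2 0.63 (0.125, and 0.048 with the block), for Nek7 0.67 (0.134) and for Sdc4 0.48 (0.134). The count of 14 rests on most of the arrays: it was 0 without control replicate 1, control replicate 2, siRNA 2 replicate 1 or siRNA 2 replicate 2, 37 without siRNA 1 replicate 1 and 23 without siRNA 1 replicate 2. It was also 0 when the 35556 probe sets were tested or when array codes were a block.

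**Figure D1:**
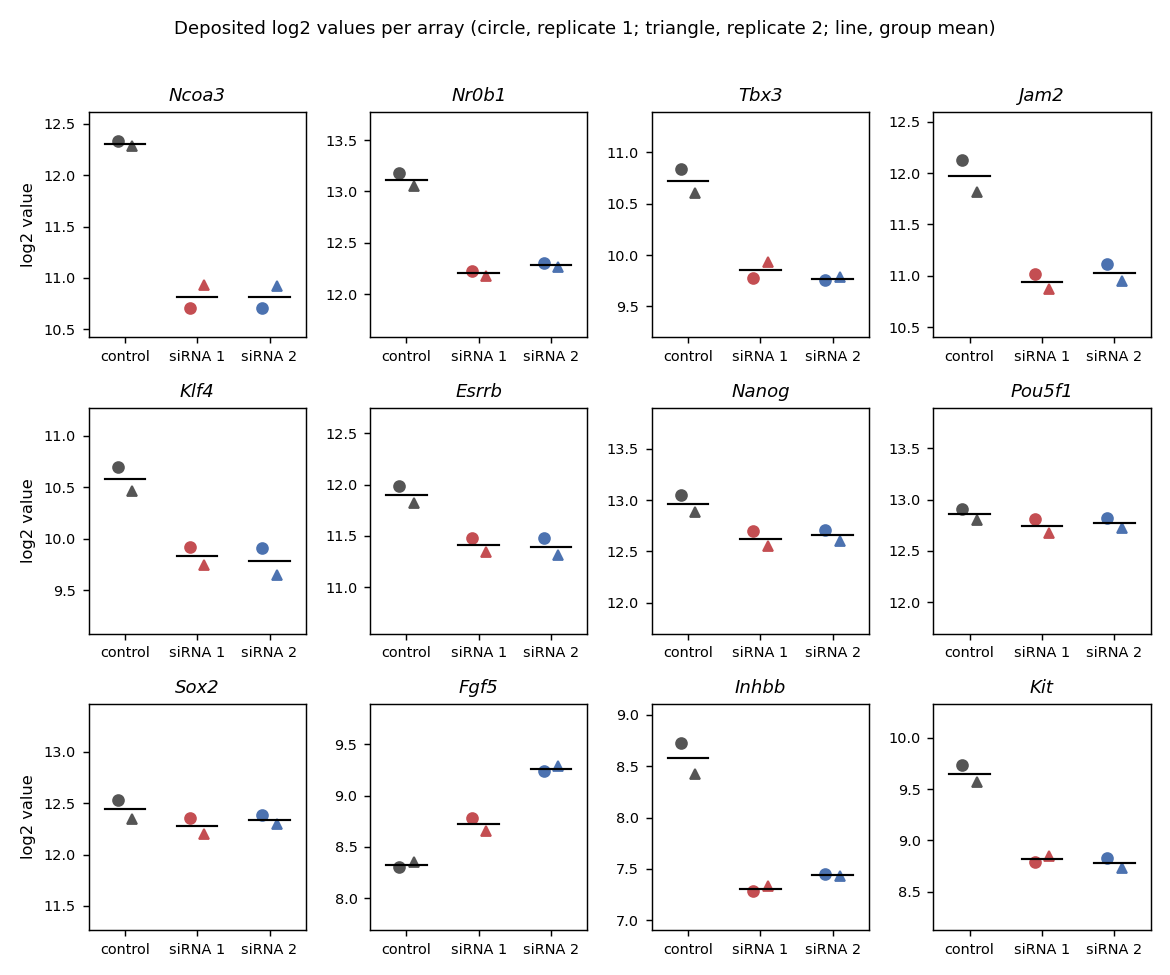
Deposited log2 values of 12 genes on each of the 6 arrays, by group; circles are replicate 1, triangles replicate 2, lines group means of 2 arrays, and each panel spans the same range. Ncoa3 falls from about 12.3 to about 10.8 with either siRNA, Nr0b1 from 13.1 to about 12.2, and Fgf5 is higher on all 4 knockdown arrays, while Pou5f1 and Sox2 overlap between groups.

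The list of core and naive pluripotency genes fell as a group. Of its 36 measured members, 33 had values below control (median log2 change -0.27). On all 4 knockdown arrays 22 were lower than on both control arrays, an order that chance gives 6.67% of genes. Over all genes, 18.9% lay without overlap in either direction, against 13.3% by chance. The camera adjusted p was 5.32e-17, and adjusted p = 0.75 with an estimated correlation. That estimate was 0.375, against the preset 0.01, so the camera p at the preset is too small if members vary together to that degree. Over all genes, 2 members fell, Nr0b1 and Tbx3; adjusted over the list alone, 16 fell and 0 rose. With the replicate block 7 fell over all genes, among them Jam2 (-0.99, adjusted p = 0.0571, and 0.018 with the block), Klf4 (-0.78, 0.134, and 0.018 with the block) and Esrrb (-0.50, 0.186, and 0.0386 with the block). These 3 and Nanog (-0.33, standard error 0.0855, adjusted p = 0.333) are among the 16. The values for Sox2 (-0.13, 0.692) and Pou5f1 (-0.10, 0.735) did not pass over all genes or over the list alone. The group's call held under each array left out, with adjusted p between 2.79e-18 and 2.05e-14, while the 16 members became 5 without control replicate 1 and 8 without siRNA 2 replicate 2, and stayed 16 without siRNA 1 replicate 2. The 2 became 0 without control replicate 1 or 2 or siRNA 2 replicate 1 or 2.

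The markers of primed epiblast, the state that follows naive pluripotency in the embryo, had a median of 0.12 over 20 members (camera adjusted p = 0.0481, and adjusted p = 0.75 with an estimated correlation). Over all genes 0 members were called; adjusted over the list alone, 6 rose and 3 fell, and 10 and 4 with the replicate block, which also called Fgf5 over all genes. Those that rose included Fgf5 and the WNT effector Lef1 (0.41), and those that fell included the ephrin receptor gene Epha4 (-0.38) and the zinc finger gene Zic5 (-0.31, and -0.15 on a second, dimmer probe set). The call was lost without control replicate 2 (0.151), siRNA 1 replicate 1 (0.238) or siRNA 2 replicate 1 (0.176), and with array medians aligned (0.0651). The 6 that rose and 3 that fell became 1 and 0 without control replicate 1, 3 and 1 without control replicate 2, and 3 and 2 without siRNA 2 replicate 2.

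Of the lists of other cell types, those of extraembryonic endoderm and trophoblast passed camera, while neural ectoderm (camera adjusted p = 0.953), primitive streak and mesoderm (0.571) and fibroblast feeder markers (0.571) did not. The extraembryonic endoderm list had 20 of 23 members above control (median 0.14, camera adjusted p = 0.039, and adjusted p = 0.809 with an estimated correlation), with 0 members called over all genes or over the list alone, and 2 that rose over the list alone with the replicate block. Its members of smallest p were Lamb1 (0.40, standard error 0.181), Thbd (0.22), Lrp2 (0.50) and Sox7 (0.19). The direction rested on control replicate 1: without it the median was -0.02 and the adjusted p 0.659. The p was 0.386 without siRNA 1 replicate 2 and 0.284 without siRNA 2 replicate 2, 0.0757 after quantile normalization and 0.0549 after cyclic loess. The trophoblast list had 15 of 18 members above control (median 0.10, camera adjusted p = 0.0343, and adjusted p = 0.75 with an estimated correlation), among them Plet1 (0.41), the T-box gene Eomes (0.29) and Ascl2 (0.30), with Tfap2c at -0.17 and 0 members called either way, and 3 that rose over the list alone with the block. Without control replicate 1 its p was 0.313, without siRNA 1 replicate 2 it was 0.0517 and without siRNA 2 replicate 2 it was 0.199.

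Genes of the cell cycle and of chromatin regulation fell as lists, by small amounts. In the cell cycle and DNA replication list, 29 of 35 members lay below control (median -0.06, camera adjusted p = 0.00145, and adjusted p = 0.75 with an estimated correlation). Cyclin D2 (Ccnd2) led them at -0.69 (standard error 0.128, adjusted p = 0.186, and 0.0197 with the block); E2f3 was at -0.41 (-0.25 on a second, dimmer probe set), Ccnd3 at -0.25 and Ccne2 at -0.31. Over all genes 0 members were called, and 1 fell adjusted over the list alone, 2 with the block. Quantile normalization raised the list's p to 0.0577 and cyclic loess to 0.164. Among the chromatin regulators 20 of 27 lay below control (median -0.05, camera adjusted p = 0.0092, and adjusted p = 0.75 with an estimated correlation). The DNA demethylase gene Tet2 was at -0.81 (standard error 0.159, adjusted p = 0.199, and 0.0212 with the block), Setdb1 at -0.31, Wdr5 at -0.27 and Mtf2 at -0.26, with 0 called over all genes and 1 adjusted over the list alone, 5 with the block. Tet2 is also a member of the core and naive pluripotency list. For the chromatin list, p was 0.118 after quantile normalization, 0.236 after cyclic loess, 0.0791 without control replicate 1, 0.0704 without siRNA 1 replicate 2 and 0.0599 without siRNA 2 replicate 2. The single members adjusted over each list alone became 0 without either control array or either siRNA 2 array; without siRNA 1 replicate 1 they became 3 for the cell cycle and 5 for chromatin.

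Immediate early genes and genes of adhesion and matrix rose as lists. Of 26 immediate early genes, 21 lay above control (median 0.12, camera adjusted p = 0.0092, and adjusted p = 0.75 with an estimated correlation), with 0 called over all genes, and 3 that rose and 0 that fell adjusted over the list alone, 5 and 2 with the block. The AP-1 member Fosl1 was at 0.40, Zfp36 at 0.35 and the phosphatase gene Dusp4 at 0.33, while Spry4 was at -0.28. The call ended without siRNA 1 replicate 1 (0.0891), and the 3 members became 0 without either control array, siRNA 1 replicate 2 or either siRNA 2 array. Of 26 adhesion and matrix genes, 20 lay above control (median 0.115, camera adjusted p = 0.00336, and adjusted p = 0.75 with an estimated correlation), with 0 called over all genes and 2 that rose adjusted over the list alone; with the block 12 rose and 2 fell. Examples were the proteoglycan Sdc4 (0.48), the protease Mmp2 (0.38), Itgav (0.29) and Cldn4 (0.26). Without control replicate 1, p was 0.165, and the 2 members became 0 without either control array, 5 without siRNA 1 replicate 1 and 1 without siRNA 2 replicate 1. This list shares Lamb1, Lama1, Lamc1, Col4a1 and Col4a2 with the extraembryonic endoderm list.

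**Figure D2:**
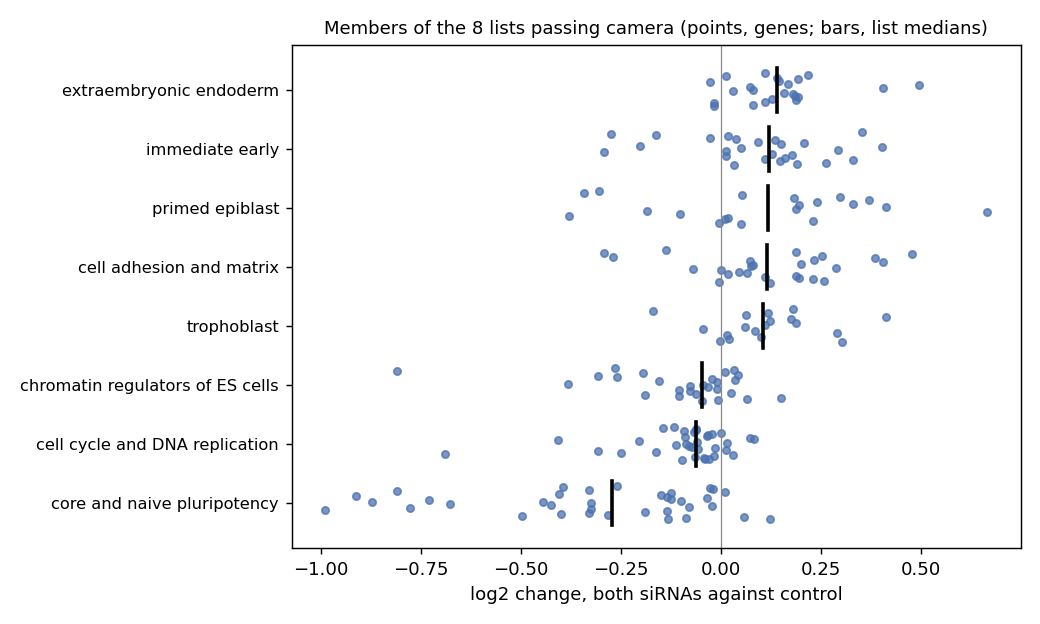
Log2 change of each measured member (points) and the median (bars) of the 8 lists that passed camera for both siRNAs against control. Most points of the core and naive pluripotency list lie left of 0, with a median of -0.27, while the other medians lie between -0.06 and 0.14.

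Among coactivators related to p/CIP and their partners, 0 of 14 members were called over all genes and 1 adjusted over the list alone, 3 with the block, and the list did not pass (camera adjusted p = 0.141). Besides Esrrb, which binds p160 coactivators, the members of smallest p were Nr5a2 (-0.44, standard error 0.134, adjusted p = 0.4), Med1 (-0.18) and Kat2b (-0.39). Esrrb and Nr5a2 are also members of the core and naive pluripotency list. In all, 19 of the 27 lists did not pass, with adjusted p from 0.0552 to 0.953.

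With siRNA 1 alone, 14 genes fell and 0 rose. The largest falls were those of Ncoa3, Necab1 (2.56-fold, log2 change -1.36, standard error 0.109), Inhbb (2.41-fold), H2-M5 (2.12-fold) and Ppp6c, a catalytic subunit of a protein phosphatase (2.07-fold), all 5 with adjusted p = 0.0452. Nr0b1 fell 1.88-fold with the same adjusted p. Myd88, the adaptor of Toll-like receptors, Crip2, Samm50 and Ube2q2, chosen after their values were seen, fell too (log2 change -0.87, -0.84, -0.79 and -0.76). No rise passed. Fosl1 was 0.74 higher (adjusted p = 0.088, and 0.029 with the replicate block), Ahnak2 0.72 (0.0894, and 0.0319 with the block), Arhgap8 0.60 (0.115, and 0.0344 with the block), Sdc4 0.55 (0.115, and 0.0391 with the block) and Gna15 0.47 (0.121, and 0.04 with the block). The replicate block called 192 lower and 49 higher genes. At an unadjusted p under 0.05 there were 1270 lower and 1152 higher genes, and an unmoderated linear model called 0. The count was 0 without either control array or either siRNA 2 array, 437 without siRNA 1 replicate 1 and 2 without siRNA 1 replicate 2.

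Of the 27 lists, 7 passed for siRNA 1, and 0 with an estimated correlation, where each of the 7 had adjusted p = 0.635. Core and naive pluripotency genes fell (camera adjusted p = 9.09e-14, median -0.29, 32 of 36 below control), with 1 member called over all genes, 10 with the replicate block, and 17 that fell adjusted over the list alone. Jam2 was at -1.03 (0.0688, and 0.0183 with the block), Tbx3 at -0.87 (0.0688, and 0.0328 with the block) and Klf4 at -0.75 (0.138, and 0.0214 with the block). Genes of cholesterol synthesis fell (0.00121, median -0.11, 16 of 19 below control; 0 called over all genes and 2 adjusted over the list alone), with Idi1 at -0.43, Hmgcs1 at -0.35 and Nsdhl at -0.31. Genes of hypoxia and glycolysis fell as well (0.0159, 17 of 24 below control; 0 called over all genes, 2 that fell adjusted over the list alone, 5 with the block, when 1 also rose), with Pdk1 at -0.71 (0.162, and 0.029 with the block) and Vegfa at -0.38. Trophoblast markers rose (0.00386, 16 of 18 above control, 0 called over all genes or the list alone, and with the block 7 that rose and 1 that fell over the list alone), with Ascl2 at 0.50 and Hand1 at 0.33. Immediate early genes rose (0.012), while cell cycle genes (4.34e-04) and chromatin regulators (0.0011) fell, with 0 members called over all genes. Adjusted over each list alone 2 immediate early genes rose, 0 cell cycle genes passed and 1 chromatin regulator fell; with the block 7 immediate early genes rose and 1 fell, 2 cell cycle genes fell and 5 chromatin regulators fell. The 2 immediate early genes became 4, with 1 that fell, without siRNA 1 replicate 1 and 1 without any of the other arrays. The 1 chromatin regulator became 6 without siRNA 1 replicate 1 and 0 without any of the other arrays. Single members called over all genes with the block were Ccnd2 (-0.66, 0.205, and 0.0242 with the block) and Tet2 (-0.95, 0.165, and 0.0214 with the block), besides Fosl1; so were Esrrb (-0.49, 0.193, and 0.0384 with the block) and Zic5 (-0.48, 0.13, and 0.0476 with the block), of which a second, dimmer probe set read -0.17. The 17 pluripotency members became 3 without control replicate 1 and 5 without siRNA 1 replicate 2; the 1 over all genes became 8 without siRNA 1 replicate 1 and 0 without any of the other arrays. The 2 cholesterol members became 0 without either control array, siRNA 1 replicate 2 or either siRNA 2 array and 1 without siRNA 1 replicate 1, and the 2 hypoxia members 0 without either control array and 1 without siRNA 1 replicate 1 or either siRNA 2 array. The call ended for the hypoxia list without control replicate 1 (0.0635) or siRNA 1 replicate 1 (0.0547) and for the immediate early list without siRNA 1 replicate 1 (0.188). After cyclic loess p was 0.0619 for cholesterol synthesis, 0.258 for hypoxia, 0.127 for chromatin and 0.163 for the cell cycle, and quantile normalization gave 0.115 for hypoxia. The block added the lists of extraembryonic endoderm (from 0.0685 to 8.56e-04), adhesion and matrix (from 0.108 to 0.0269), two-cell-like genes (from 0.0533 to 0.0199) and ribosomal proteins (from 0.0533 to 0.033).

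With siRNA 2 alone, limma called 0 genes, at a smallest adjusted p of 0.0742, that of Ncoa3. An unadjusted p under 0.05 was reached by 597 lower and 449 higher genes, against 997 by chance in all; an unmoderated linear model called 0, and the replicate block called 22 lower and 4 higher. The values nearest to the threshold were those of Inhbb (-1.14, standard error 0.112), Gli2 (-0.87), Kit (-0.87), Nr0b1 (-0.83) and Fgf5 (0.93, standard error 0.0835), each with adjusted p = 0.0906, and 0.048 with the block. Lefty1, an antagonist of Nodal, was 0.81 higher (0.183, and 0.0484 with the block), Ap3b2 0.56 (0.183), Oasl2 0.58 (0.206) and Nek7 0.70 (0.251). The count was 10 without siRNA 1 replicate 1, 10 without siRNA 1 replicate 2 and 0 without any of the other 4 arrays.

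For siRNA 2, 8 lists passed, and 0 with an estimated correlation. Core and naive pluripotency genes fell again (camera adjusted p = 2.72e-16, and adjusted p = 0.518 with an estimated correlation; median -0.28, 32 of 36 below control), with 0 members called over all genes, 4 with the block, and 13 that fell adjusted over the list alone. Jam2 was at -0.95 and Mras at -0.81, each with 0.048 with the block, and Tbx3 at -0.96. Primed epiblast markers rose (3.42e-04, and adjusted p = 0.518 with an estimated correlation; 15 of 20 above control). Adjusted over the list alone 4 rose, 7 with the block, and 1 fell, with the homeobox gene Otx2 at 0.57 and Epha4 at -0.47, and 0 were called over all genes. Targets of LIF and STAT3, the pathway that keeps these cells naive, fell (0.00344, and adjusted p = 0.557 with an estimated correlation; 14 of 20 below control), with 5 that fell adjusted over the list alone, 6 with the block, when 1 also rose, and 0 called over all genes. Klf4 was at -0.80 (0.272, and 0.048 with the block), the receptor gene Lifr at -0.49 and Socs3 at -0.32. A second, dimmer probe set of Socs3 read -0.09. Klf4 is among the members that this list shares with the core and naive pluripotency list. Adhesion and matrix genes rose (5.73e-06, and adjusted p = 0.575 with an estimated correlation), as did cholesterol synthesis genes (0.00388, 0.518), immediate early genes (0.0344, 0.655) and interferon response genes (0.0491, 0.518), while cell cycle genes fell (0.0441, 0.905). Of these 5 lists 0 members were called over all genes; adjusted over each list alone 2 adhesion genes, Cyp51 among the cholesterol genes (0.42) and Oasl2 among the interferon genes rose, 1 immediate early gene rose and 1 fell, and 0 cell cycle genes passed. With the block 11 adhesion genes rose over the list alone, 3 interferon genes rose and 2 fell, 3 immediate early genes rose and 2 fell, and 2 cell cycle genes fell, Ccnd2 among them (-0.72, 0.385, and 0.048 with the block). Without the block, leaving out a control or siRNA 2 array gave 0 in these 4 lists, except for 1 interferon gene without siRNA 2 replicate 2. Members of the interferon list went both ways, with Ifit1 at 0.37 but Oas1a at -0.50 and Oas2 at -0.39. With the block, extraembryonic endoderm (from 0.0539 to 0.00398) and fibroblast feeder markers (from 0.0582 to 0.0399) passed as well. The 13 pluripotency members became 6 without control replicate 1, 7 without siRNA 2 replicate 1 and 6 without siRNA 2 replicate 2. The 4 primed epiblast markers became 1 without control replicate 1 or siRNA 2 replicate 1, and the 5 LIF targets became 0 without control replicate 1 or siRNA 2 replicate 2 and 1 without control replicate 2 or siRNA 2 replicate 1. Calls ended for cell cycle genes without control replicate 1 (0.293) or siRNA 2 replicate 2 (0.514), for cholesterol synthesis without control replicate 2 (0.0833) or siRNA 2 replicate 1 (0.157), and for immediate early genes without control replicate 1 (0.255) or siRNA 2 replicate 2 (0.334). For the interferon list p was 0.0531 and 0.133 without control replicate 1 and 2, and 0.114 and 0.0646 without siRNA 2 replicate 1 and 2. Quantile normalization gave 0.142 for the cell cycle and 0.127 for interferon, and cyclic loess 0.198 and 0.116.

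No gene was called by both siRNAs, since limma called 0 for siRNA 2. With the replicate block 21 genes were lower and 1 was higher with both, and 0 were called in opposite directions. Independent lists of these sizes would share 0.212 and 0.00983, numbers that leave out the shared control arrays, so the excess is not read as a shared effect and part of it may come from the shared controls. By the rule the largest falls of the 21 were those of Ncoa3, Inhbb, H2-M5, Jam2 and Stmn3, and the gene that was higher was Dsp, which encodes desmoplakin (0.84 and 0.66). Across genes, which are not independent replicates, the changes with the siRNAs correlated at Pearson r = 0.596 and Spearman rho = 0.552. In 100 simulations of unchanged groups with shared controls, the means were 0.5 and 0.476 and the highest 0.52 and 0.494. The covariance was 0.0144 against a simulated 0.00656, a difference of 0.00788. The same sign was seen for 69.4% of genes, against 66.7%. Simulated noise was independent between genes and arrays, which makes the simulated range narrow. Values beyond that range therefore do not show a shared effect. Without siRNA 2 replicate 2, r was 0.395, and without control replicate 2 it was 0.755. The number of genes called by both was 9 without siRNA 1 replicate 1 and 1 without siRNA 1 replicate 2.

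Between the siRNAs limma called 0 genes, at a smallest adjusted p of 0.0851. An unadjusted p under 0.05 was reached by 670 genes higher and 706 lower with siRNA 2 than with siRNA 1, against 997 by chance in all; an unmoderated linear model called 0, and the replicate block called 14 higher and 1 lower. Nearest to the threshold was Myd88, 2.01-fold higher with siRNA 2 than with siRNA 1 (log2 difference 1.00, standard error 0.0766, adjusted p = 0.0851, and 0.0395 with the block). It was followed by Arpc5 (1.08, 0.146), Crip2 (0.83, 0.146), Samm50 (0.77, 0.146) and Ppp6c (0.91, 0.208), of which Crip2, Samm50 and Ppp6c had 0.0479 with the block. In the other direction, Jpt1 differed by -0.75 (0.208, and 0.0479 with the block), Fosl1 by -0.68 (0.296), Ptges by -0.45 (0.332), Saa1 by -0.54 (0.376) and Aadac by -0.42 (0.376). The pluripotency list did not differ past the threshold (camera adjusted p = 0.124, median 0.03). Differences were 0.03 for Nanog, -0.09 for Tbx3 and -0.05 for Klf4, with standard errors of 0.0987, 0.107 and 0.129. The count was 2 without siRNA 1 replicate 1 and 0 without any of the other arrays.

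The list that differed most between the siRNAs was cholesterol synthesis, which was higher with siRNA 2 in 18 of 19 members (median 0.23, camera adjusted p = 9.52e-11, and adjusted p = 0.28 with an estimated correlation). Adjusted over the list alone 3 members were higher, Cyp51 (0.55, standard error 0.0878), Hmgcs1 (0.40) and Msmo1 (0.38), and over all genes 0; with the block 8 were higher over the list alone. These 3 became 0 without siRNA 2 replicate 1, 1 without siRNA 2 replicate 2 and 5 without siRNA 1 replicate 1. Primed epiblast markers were higher with siRNA 2 (0.0142, and adjusted p = 0.575 with an estimated correlation), with 4 members higher adjusted over the list alone and 0 over all genes, led by Fgf5 (0.54), Otx2 (0.48) and Zic5 (0.36), whose second probe set read -0.17 with siRNA 1 and -0.13 with siRNA 2. Hypoxia and glycolysis genes were higher (0.00187, and adjusted p = 0.646 with an estimated correlation), with 0 members over all genes and 2 adjusted over the list alone, Pdk1 (0.88, adjusted p = 0.31, and 0.0479 with the block) and Pkm (0.33). Trophoblast markers were lower (0.0224, and adjusted p = 0.652 with an estimated correlation), with 0 members called over all genes or the list alone, 6 lower over the list alone with the block, and Cdx2 at -0.47, Gata2 at -0.46 and Hand1 at -0.44. Fibroblast feeder markers were higher by camera, with 12 of 21 above 0 (median 0.03, camera adjusted p = 0.0493, 0.06 with the block, and adjusted p = 0.652 with an estimated correlation), with 0 members over all genes and 3 higher adjusted over the list alone, 4 with the block, when 1 was also lower, among them the actin gene Acta2 (1.49, standard error 0.351, adjusted p = 0.481), while Col3a1 was at -0.27. Calls ended for primed epiblast without siRNA 1 replicate 2 (0.0504) or siRNA 2 replicate 1 (0.124), for trophoblast without siRNA 1 replicate 1 (0.0585) or siRNA 2 replicate 1 (0.221), for hypoxia without siRNA 2 replicate 1 (0.221), and for fibroblast markers without siRNA 1 replicate 1 (0.647) or siRNA 2 replicate 2 (0.314). The 4 primed epiblast members became 1 without either control array, 2 without siRNA 1 replicate 2 or siRNA 2 replicate 2 and 0 without siRNA 2 replicate 1. The 2 hypoxia members became 0 without siRNA 2 replicate 1 and 1 without any of the other arrays, and the 3 fibroblast members 0 without either siRNA 2 array. Quantile normalization gave 0.0598 for primed epiblast and 0.101 for fibroblast markers, and cyclic loess 0.0967 for each.

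**Figure D3:**
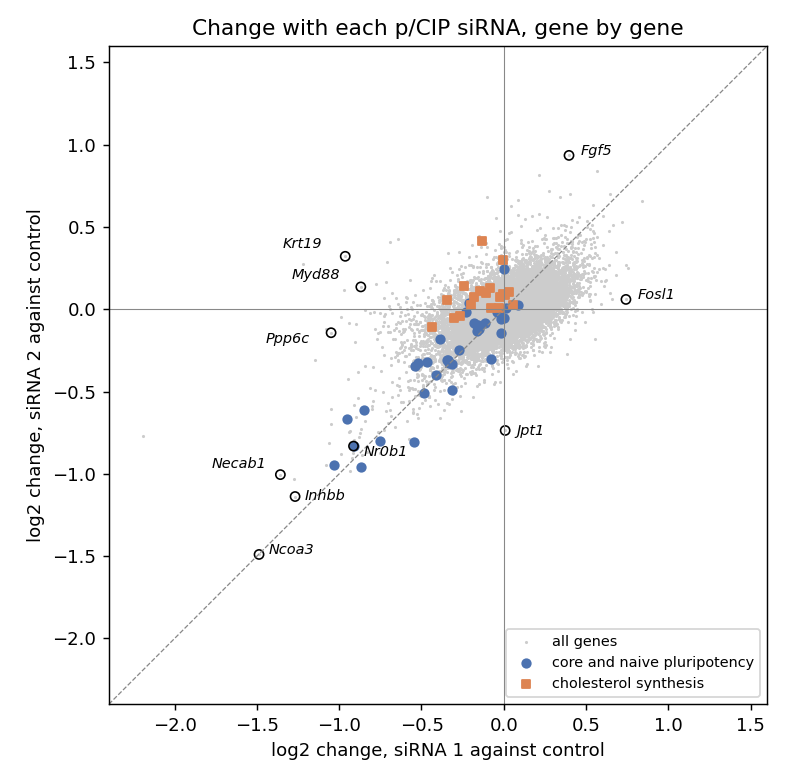
Log2 change of each of the 19938 genes with siRNA 1 (horizontal axis) and siRNA 2 (vertical axis) against the same control arrays, with the line of equal change dashed. Pluripotency genes lie along the line toward the lower left, cholesterol synthesis genes lie above it, and Krt19, Myd88 and Ppp6c lie at -0.96, -0.87 and -1.05 with siRNA 1.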

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

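The tests of a lower share of stem cells, of unequal knockdown, and of array siRNA 1 replicate 2 as the source of the genes lower with siRNA 1 were chosen only after the result was seen, the first of them in place of an earlier comparison of the list's most changed genes with Pou5f1 and Sox2, since genes picked for their change exclude nothing.

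The siRNAs differed in 11 of the 27 lists by the test of the difference itself (camera adjusted p under 0.05), and in 0 of them with an estimated correlation (adjusted p from 0.28 to 0.652). Cholesterol synthesis genes had a median log2 difference of 0.226, siRNA 2 minus siRNA 1. Primed epiblast markers had a median of 0.029, with a mean of 0.103 carried by Fgf5, Otx2, Zic2 and Zic5. Trophoblast markers had a median of -0.086, fibroblast feeder markers of 0.034, and hypoxia and glycolysis genes of 0.051. Ribosomal protein genes were higher with siRNA 2 in 21 of 21 members (median 0.062, camera adjusted p = 0.015), but not past the threshold without siRNA 1 replicate 2 (0.909) or siRNA 2 replicate 1 (0.221). Chromatin regulators were higher in 21 of 27 (median 0.069, 0.00315), and p was 0.41 without siRNA 1 replicate 2 and 0.199 without siRNA 2 replicate 1. Two-cell-like genes had a median of 0.14 over 8 members (0.0187), with p of 0.596 and 0.22 without the same arrays. For cell cycle genes the median was 0.033 (0.0262), with p of 0.791 and 0.342 without them. Interferon response genes had a median of 0.038 (0.0305), and p was 0.251 without siRNA 1 replicate 1 and 0.0763 without siRNA 2 replicate 1. Adhesion and matrix genes had a median of 0.059 (0.0483, and 0.0996 with the replicate block), and p was 0.488 without siRNA 1 replicate 1 and 0.39 without siRNA 2 replicate 2. In these last 6 lists 0 members were called by limma, over all genes or adjusted over the list alone; with the replicate block 5 interferon genes, 2 two-cell-like genes and 1 adhesion gene were higher over the list alone. Without siRNA 1 replicate 1 the list alone gave 3 two-cell-like genes and 1 cell cycle gene.

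Core and naive pluripotency genes were lower in the knockdown arrays, with a median log2 change of -0.27. Differences between arrays that depend on the level of a gene are argued against, since 0% of 10000 random lists matched on mean level had a median as low and the lowest was -0.097; so is array siRNA 1 replicate 2, without which the median was -0.224. A lower share of stem cells would lower alike only transcripts that the other cells lack. Of the 36 members, 10, Pou5f1 among them, lay more than 2 standard errors above the list's median, against 1.56 by chance for independent members. The list was not restricted to such transcripts, and its estimated correlation was 0.375. The test therefore cannot decide whether a lower share of stem cells is the whole cause. For part of the fall it stays open, since extraembryonic endoderm markers were above control in 20 of 23 (camera adjusted p = 0.039, 4.23e-04 with the replicate block, 0.809 with an estimated correlation) and trophoblast markers in 15 of 18 (0.0343, 0.00614, 0.75), calls that ended without control replicate 1 (0.659 and 0.313), siRNA 1 replicate 2 (0.386 and 0.0517) or siRNA 2 replicate 2 (0.284 and 0.199), and replicate 2 against replicate 1 paired higher endoderm markers (median 0.382) with lower pluripotency genes (-0.111). Only 0 of the 23 endoderm and 3 of the 18 trophoblast markers were higher on all 4 knockdown arrays than on both control arrays. Chance gives this order to 6.67% of genes. Loss of p/CIP, which the design names, may lower the pluripotency genes, as a hypothesis found in the same data, and the reading of the 2 control arrays that both siRNAs share stays open too.

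A group of 14 genes was lower with siRNA 1 than with siRNA 2 when the replicate number was a block, among them Krt19 (difference 1.29), Cnn1 (1.07) and Myd88 (1.00), of which all but Myd88 were chosen after their values were seen. On the replicate 2 arrays, 161 genes were at least 1.5-fold lower with siRNA 1 than with siRNA 2. Of these, 31 were as much lower on the replicate 1 arrays and 0 as much higher. This argues against array siRNA 1 replicate 2 as the whole source of differences among the 161. The 14 were among the 31, but they were called from both pairs of arrays. Their place there was thus nearly fixed by selection and decides nothing for them. Under the same limit, their median difference from siRNA 2 was 0.921 for siRNA 1 replicate 1 and 0.829 for replicate 2. Unequal knockdown of the transcript by 0.496 or more, the fall of Ncoa3 divided by 3, is argued against. The Ncoa3 difference was -0.003 (95% interval -0.267 to 0.262). Smaller differences within this interval, and differences in p/CIP protein, which was not measured here, stay open. An effect of siRNA 1 on transcripts other than its target may account for the group: the median was -0.763 with siRNA 1 and 0.146 with siRNA 2, next to the bound of 0.15 set for it. With siRNA 2, 7 of the 14 lay over 0.15 above control, so that part of their difference may be a rise with siRNA 2; siRNA sequences were not used here, so matches to these transcripts stay untested.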

How the results depend on the processing

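Cyclic loess, alone or with the replicate block, and the replicate block with array 2 of siRNA 1 left out were chosen only after the result was seen. Ncoa3 was lower with the siRNAs in every setting, and the pluripotency list kept its direction, and its call by camera at the preset correlation, under each scaling, with the lowest levels left out, with the mean of a gene's probe sets, with each block and without each array, but not its call by camera with an estimated correlation, or by fry without the block (0.256, 0.235 and 0.285 for both siRNAs, siRNA 1 and siRNA 2). With the replicate block fry passed for this list, and for adhesion and matrix, at an adjusted p of 0.0203, 0.0186 and 0.0309 each. The numbers of called genes depended strongly on the model of the spread, and the cause was not tested. Counts follow in the order both siRNAs, siRNA 1, siRNA 2, siRNA 2 against siRNA 1, and genes changed by both siRNAs, which were 14, 14, 0, 0 and 0 as deposited. The replicate block gave 68, 241, 26, 15 and 22, and changed no other call of a gene value or list given in the text than those given with it. Trend and robust eBayes gave 71, 150, 17, 23 and 13, and leaving out genes under the median level, with fewer genes tested, 38, 85, 11, 4 and 10. Cyclic loess gave 37 for siRNA 1, 2 for siRNA 2 and 1 for genes changed by both siRNAs. With the replicate block it gave 268, 575, 58, 44 and 53. The replicate block with array 2 of siRNA 1 left out gave 215, 107, 108, 4 and 53. Limma gave 0 for both siRNAs and for siRNA 1 with the array code block and with every probe set tested, as did the unmoderated linear model. Array weights gave 0 for siRNA 1 and 15 for siRNA 2; only the arrays of the groups compared gave 0 and 10. Quantile normalization gave 2 for siRNA 2 and 1 for genes changed by both siRNAs. Array medians aligned gave 26 for siRNA 1. They gave 1 each for siRNA 2, for siRNA 2 against siRNA 1 and for genes changed by both siRNAs. An adjusted p under 0.10 gave 42, 12, 1 and 10 from siRNA 1 onward, and an unadjusted p under 0.01 with a fold of at least 1.5 gave 68, 133, 56, 48 and 37.

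With 1 array left out, counts ran from 0 to 37, 0 to 437, 0 to 10, 0 to 2 and 0 to 9: for both siRNAs 37 without siRNA 1 replicate 1, 23 without siRNA 1 replicate 2 and 0 without any other; for siRNA 1 437 and 2 without those arrays and 0 without any other; for siRNA 2 10 without either of them; between the siRNAs 2, and by both 9, without siRNA 1 replicate 1, and by both 1 without siRNA 1 replicate 2. A group left with 1 array was assumed to vary like the others. Ncoa3 stayed between -1.54 and -1.433, and its call ended at -1.488 with the unmoderated linear model (0.366), the array code block (0.157) and every probe set tested (0.166), and without control replicate 1 (0.62), control replicate 2 (0.248), siRNA 2 replicate 1 (0.146) or 2 (0.0969). The correlation between the siRNAs ran from 0.395 without siRNA 2 replicate 2 to 0.755 without control replicate 2. Of the other alternatives for 137 named gene values, 2325 kept direction and side of the threshold, 271 passed it, 199 no longer did and 13 changed sign; for 34 called lists these numbers were 406, 0, 171 and 1. Values that changed sign were the extraembryonic endoderm median (-0.022) and Sox7 (-0.004) without control replicate 1, against highs of 0.306 and 0.387 without control replicate 2. Between the siRNAs they were Ncoa3 (0.023 with medians aligned, 0.108 without siRNA 1 replicate 2, against -0.114 without siRNA 1 replicate 1, 0.101 without siRNA 2 replicate 1, 0.069 with the block and array 2 of siRNA 1 left out), Nanog (-0.011 with quantile normalization, -0.016 with cyclic loess with or without the block, -0.044 without siRNA 1 replicate 2, -0.02 without siRNA 2 replicate 1), Tbx3 (0.043 with the block and array 2 of siRNA 1 left out) and Klf4 (0.041 without siRNA 1 replicate 1, 0.083 without siRNA 2 replicate 2, against -0.178 without siRNA 2 replicate 1). Signal over background was not analysed here, and 2 arrays per group limit the precision.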

Other observations

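The comparison of the replicate numbers, and both tests of what the arrays of a number share, were chosen only after the result was seen.

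Of 27 lists, 12 differed between arrays of replicate 2 and replicate 1 (camera adjusted p under 0.05), the extraembryonic endoderm markers with the smallest p. Of the 23 measured markers, 22 were higher in replicate 2 (median log2 difference 0.382, camera adjusted p = 1.97e-10, and adjusted p = 0.382 with an estimated correlation; fry adjusted p = 0.0256). Lama1, a laminin chain of the basement membrane, was at 0.96 (standard error 0.089, adjusted p = 0.0858), the endocytic adaptor Dab2 at 0.69 (0.0858), the transcription factor genes Gata6 at 0.68 and Gata4 at 0.51 (0.108 each), and the receptor genes Cubn at 0.67 (0.0955) and Lrp2 at 0.64 (0.0858), none of the 6 past the threshold and all chosen after their values were seen. In limma with group and replicate number as terms, 5 genes were higher in replicate 2 and 0 were lower, against 3087 and 1795 at an unadjusted p under 0.05. These 5, chosen after their values were seen, were Glipr1 (1.65), Nxf7 (1.05), the prostaglandin transporter gene Slco2a1 (1.05), the proteoglycan gene Srgn (0.91), itself 1 of the endoderm markers, and Hs3st1 (0.69).

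Other lists were higher in replicate 2 as well: adhesion and matrix (median 0.121, camera adjusted p = 0.001, 21 of 26), trophoblast (0.153, 0.0119, 14 of 18), fibroblast feeder (0.166, 0.0138, 17 of 21) and primitive streak and mesoderm (0.109, 0.0473, 16 of 19), each with an adjusted p of 0.383 or 0.575 with an estimated correlation. By fry, adhesion and matrix passed (adjusted p = 0.0256). Trophoblast (0.119), fibroblast feeder (0.171) and primitive streak and mesoderm (0.207) did not. Core and naive pluripotency genes were lower in replicate 2 (median -0.111, 5 of 36 above 0, camera adjusted p = 7.33e-08, and adjusted p = 0.382 with an estimated correlation; fry adjusted p = 0.0417). The 6 other lists were lower, namely germline, chromatin regulators, ribosomal proteins, cell cycle, hypoxia and two-cell-like genes, with medians from -0.116 to -0.051, and with an estimated correlation their adjusted p was 0.383 for chromatin regulators and 0.575 for the other 5.

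Arrays with the same replicate number deviated from their group means together. A trend of the deviations with the level of a gene is argued against as the whole cause, since the correlations stayed between 0.372 and 0.42 once it was removed. More cells with extraembryonic endoderm transcripts in the replicate 2 samples may be part of it, since the lowest of the 3 group medians of the markers was 0.375, with 0.389 in control and 0.437 with siRNA 1, and 21 of 23 markers were higher in each group. The most abundant markers, chosen after their values were seen, were Sparc (12.75 in replicate 1 and 13 in replicate 2), Srgn (11.02 and 11.93) and Lamc1 (11.12 and 11.28), and 6 of the 23 are also in another list. Higher transcription of these genes in the stem cells themselves was not tested and stays open. Markers of other cell types were higher too by camera at the preset correlation, but did not pass by fry. Whether the difference is one of endoderm alone therefore stays open.

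The 13767 probe sets without a single gene name held 0 called by limma in any comparison, with or without the replicate block. At an unadjusted limma p under 0.05 there were 1001 for both siRNAs against control (7.27%) and 1364 for siRNA 1 against control (9.91%). There were 641 for siRNA 2 against control (4.66%) and 896 between the siRNAs (6.51%).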
